A study of Mus musculus with 15 samples.

How the data were processed

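Open chromatin was profiled by bulk ATAC-seq in 15 libraries from 5 sorted mouse progenitor populations, with 3 libraries per population. Per the labels, libraries were prepared with the Omni-ATAC protocol and a Nextera kit from 1000 cells each. Sequencing yields fragments cut by the Tn5 transposase in accessible DNA, so the number of reads in a region rises with its accessibility. The authors deposited a table of raw counts per region and library, without normalization, and its 15 columns carried the sample titles. Trim Galore, FastQC, Bowtie2, SAMtools, Picard and MACS2 are named with the mouse build mm9 in the submitters' processing notes, without versions or order. The tool that counted reads, any shift of reads to the transposase cut site, the handling of duplicate reads and the choice between pooled and separate peak calling are not given in the sources used here.

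The table held 233383 regions with a median width of 387 bp and a range from 200 to 4141 bp, and no neighbouring regions overlapped. Coordinates are given as the file states them, on mm9. The gene annotation at hand was on another assembly, and no coordinates were converted, so regions are named by position and carry no gene, exon or intron. Gene list tests and motif tests planned before the data were examined were therefore not run. Groups came from the cell type in the labels, and the replicate number came from the titles.

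Tests were run on the counts as deposited with edgeR 4.0.16 in R 4.3.3. Regions were kept by filterByExpr with a minimum count of 10 and a minimum total count of 15, which left 172609 regions (74.0%) holding 97.4% of all counts. Library sizes were scaled by the trimmed mean of M values (TMM), with factors from 0.886 to 1.20. One quasi-likelihood model with a mean for each population was fitted to all 15 libraries. An F test asked whether a region differed among the 5 populations, and 10 contrasts compared them in pairs. A region was called at a Benjamini-Hochberg adjusted p under 0.05 and a log2 fold change of at least 1, or for the F test a range of at least 1 between population means. A region specific to a population was called higher in it than in each of the other 4. Windows of 1 Mb were tested for an excess of specific regions over the tested regions they held (hypergeometric test, Benjamini-Hochberg adjustment over windows and populations). Levels are given as CPM, the counts of a region per 1000000 of the TMM-scaled library size. Standard errors of log2 fold changes were derived from the F statistic of the contrast.

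The regions named were chosen by a rule fixed before the data were examined. For each population, these were the 5 specific regions with the largest value of the smallest of their 4 log2 fold changes, among regions with a mean of at least 1 log2 CPM in that population. For each pair, these were the 2 regions with the largest fitted change in each direction, with no overlap between the libraries of both populations. With no gene names on the build of the file, this is the form of the rule that names regions by position. With 0 counts in the lower population, the fold is given as a lower bound against 3 counts over the population. With 1 to 3 counts, the ratio is given with a 95% exact binomial interval of the counts. PCR reads without molecular identifiers are not independent molecules, so the intervals cover counting error only. The bounds leave out counting error in the higher population and are not 95% limits. The lower 95% limit of the exact interval lay below them. It was 10.3-fold where the bound was 13.02-fold, and 494-fold where the bound was 608.2-fold.

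Total counts per library ran from 3413966 to 16610848. A count of 3 over a population corresponded to 0.252 CPM in DN3, the shallowest population, and to between 0.102 and 0.145 CPM in the other 4. The test was checked on simulated counts with the real library sizes, the fitted trend of dispersion and the overall region means. Populations did not differ, except that 200 of 172609 regions were raised in a single population, 100 by 2-fold and 100 by 4-fold. At 4-fold, 82% of the raised regions were recovered as specific for CFU-E, 87% for DN3, 89% for MkP, 91% for NMP and 89% for ProB. At 2-fold, which equals the fold threshold, 13%, 11%, 8%, 8% and 7% were recovered. Of the unchanged regions, 0 were called specific and 2 to 4 per simulation were called by the F test. The simulated spread follows the model's own trend, so regions more variable than the trend were not checked. With few regions changed, scaling under widespread differences was not checked either.

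Alternatives fixed before the data were examined were median-of-ratios size factors, total counts alone, limma-voom (limma 3.58.1) after quantile normalization, no count filter, DESeq2 1.42.0, no minimum fold change, removal of chromosomes X, Y and M, a replicate block, fits of 6 libraries per pair, and removal of each library in turn. Thinning of all libraries to 3413966 counts, 1 region per 5 kb, and windows moved by 0.5 Mb were chosen after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.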

Results

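The data describe accessible chromatin in 5 blood progenitor populations of C57BL/6 mice aged 8 to 12 weeks, with 3 libraries of 1000 sorted cells for each. CFU-E are committed erythroid progenitors, sorted from the LK gate without CD41, CD16/32 or CD150 and with CD105. MkP, progenitors of megakaryocytes, were taken from the same gate with CD150 and CD41. NMP were LK cells without CD41 and CD150, positive for CD16/32 and negative for Gata1, the latter a transcription factor of erythroid and megakaryocytic cells. ProB, early B cell precursors, were B220+, CD19+, cKit+ and IgM-. DN3 were lineage-negative CD4-, CD8-, CD44- and CD25+ cells, the surface phenotype of an early T cell stage that is usually sorted from thymus. The labels list bone marrow as the source of all 15 libraries, and the tissue of the DN3 cells could not be checked here. If it was another tissue, its effect cannot be told apart from that of the population in comparisons with DN3.

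The total count in regions was 8550186, 6949515 and 8883644 in the 3 CFU-E libraries and 4383387, 3413966 and 3585503 in DN3. It was 7888626, 7293696 and 9855294 in MkP, 8869089, 16610848 and 5781670 in NMP, and 8534949, 7599875 and 7273057 in ProB. Of the 233383 regions, 28.3% ± 2.94 (SD, n = 3) had no count in a DN3 library, against 6.27% ± 0.665 in an MkP library. The 3 libraries of a population correlated at a Pearson r of 0.937 to 0.973 across regions on the log2 CPM scale, where regions are not independent replicates. At regions with at least 20 counts over 2 replicates, their counts differed with a chi-square of 1.09 to 1.47 per region, where 1 is counting error alone. Regions with fewer counts were left out of this measure. The labels do not state that replicates came from separate animals, so p-values rest only on the spread between these samples, which may be technical. The estimated prior degrees of freedom were infinite, so each region took the spread of the trend over regions of similar level. A region's own replicate spread therefore did not enter its p-value or its standard error.

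The 5 populations formed separate clusters. On the first principal component (36.5% of variance), CFU-E lay apart from DN3 and ProB. NMP lay at the far end of the second (29.6%), ProB and DN3 at opposite ends of the third (17.7%), and MkP at the end of the fourth (8.60%). Between populations, MkP and NMP were the closest pair, with a mean r of 0.705 ± 0.0230 (SD over 9 pairs of libraries), followed by DN3 and ProB at 0.653 ± 0.0100. CFU-E and NMP were the most distant, at 0.366 ± 0.00919.

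**Figure D1:**
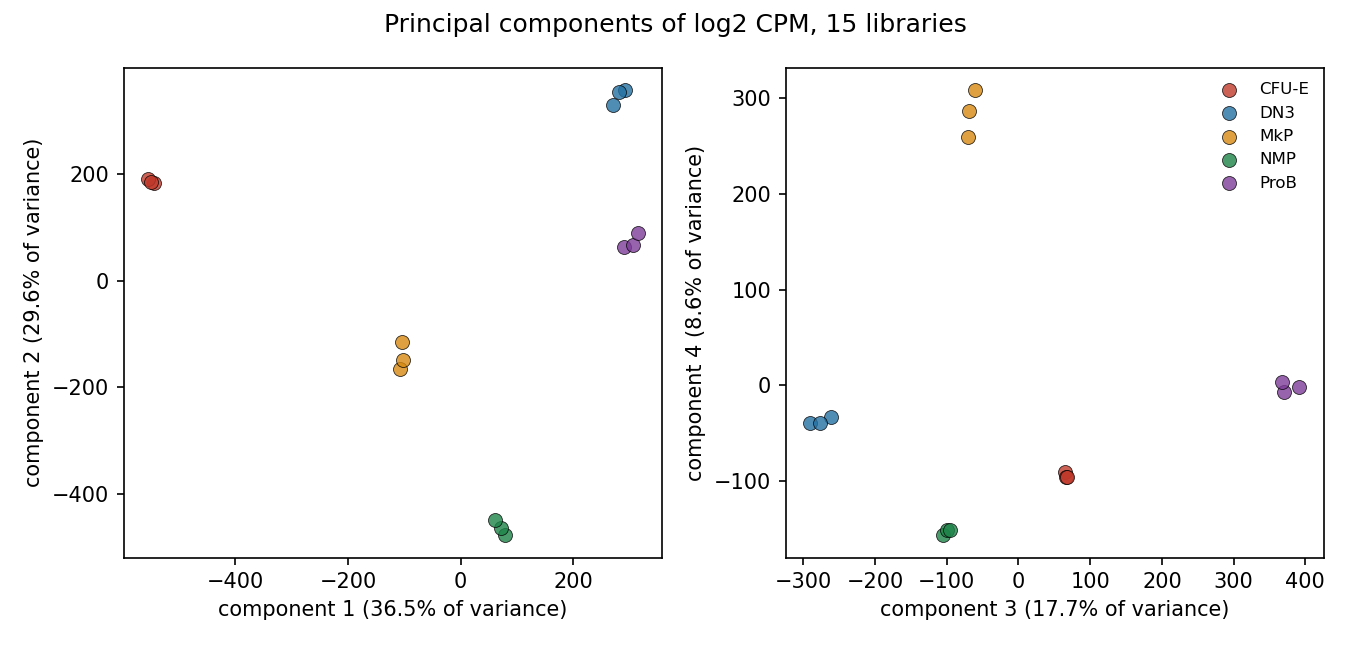
Principal components 1 to 4 of log2 CPM over the tested regions, 1 point per library, coloured by population, with the percent of variance on each axis (scores without unit). The 3 libraries of each population lie together, and MkP separates on component 4 (8.60% of variance).

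Accessibility differed among the populations at 158347 of 172609 tested regions (91.7%; edgeR's quasi-likelihood F test with Benjamini-Hochberg adjustment, and a range of at least 1 on the log2 scale). The 14262 regions not called were wider, with a median of 908.5 bp against 472 bp for called regions. They were also more accessible, with a median mean level of 12.5 CPM against 1.91 CPM.

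CFU-E had 25544 specific regions, 14.8% of those tested. These regions held 24.8% ± 0.206 (SD, n = 3) of the CFU-E counts and had a mean level of 10.8 ± 0.229 CPM in CFU-E. MkP came next with 1.81 ± 0.0217 CPM, and the other 3 populations lay between 0.923 and 1.052 CPM. MkP was the population with the next highest level at 59.0% of the CFU-E specific regions. Chromosome 13, 102342876 to 102343759, had 23.0 ± 2.33 CPM in CFU-E and 0.127 ± 0.136 CPM in MkP, a log2 fold change of 7.21 ± 0.32 (SE; adjusted p = 2.08e-68, edgeR's quasi-likelihood test). Chromosome 9, 42179707 to 42180628, had 20.9 ± 1.89 CPM and a log2 fold change over MkP of 7.05 ± 0.33. The region at chromosome 4, 9588131 to 9588481, had 16.1 ± 2.03 CPM, 152-fold the MkP level (95% counting interval 51.6 to 741, from 3 counts in MkP). A level of 15.8 ± 1.35 CPM was found at chromosome 8, 27157861 to 27158352, 156-fold that in NMP (53.0 to 761). At chromosome 9, 35343474 to 35343800, CFU-E had 3.26 ± 0.289 CPM while the other 4 populations had 0 counts, which put CFU-E at least 13.02-fold higher than DN3. CFU-E specific regions were in excess in 154 of 2451 windows of 1 Mb, which held 19.97% of them and 10.2% of the tested regions, led by chromosome 4, 59000001 to 60000000, with 87 of 262 tested regions (adjusted p = 9.42e-11, hypergeometric test). In a run on chromosome 3, 37381659 to 37452872, 13 consecutive tested regions were specific to CFU-E.

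DN3 had 16686 specific regions (9.67%), which held 16.1% ± 1.10 of the DN3 counts. Their mean level was 9.07 ± 0.637 CPM in DN3 and at most 1.31 ± 0.0436 CPM elsewhere, in ProB. The next rank was spread over the populations, with ProB at 30.6% of these regions, CFU-E at 27.2%, MkP at 21.6% and NMP at 20.6%. At chromosome 15, 63086755 to 63087741, DN3 had 59.0 ± 9.19 CPM and CFU-E 0.228 ± 0.265 CPM, a log2 fold change of 7.87 ± 0.27 (adjusted p = 7.57e-184, edgeR's quasi-likelihood test). Chromosome 17, 52421407 to 52422061, had 26.2 ± 3.24 CPM, 369-fold the MkP level (101 to 3063, from 2 counts in MkP). Chromosome 5, 93292810 to 93293509, had 31.5 ± 8.06 CPM, 319-fold that in ProB (87.6 to 2641). Chromosome 12, 109166141 to 109166770, had 42.0 ± 4.80 CPM, 287-fold that in ProB (97.7 to 1397). Chromosome 1, 128081735 to 128082078, had 4.91 ± 1.35 CPM in DN3 and 0 counts in the other 4 populations, at least 34.0-fold higher than in CFU-E (adjusted p = 1.43e-20, edgeR's quasi-likelihood test). DESeq2 did not call this region (adjusted p = 0.192, against 5.43e-12 or less under the other alternatives). Its smallest fitted log2 fold change was 7.57 in DESeq2 and 8.17 in the main fit. The window with the lowest p of any population was chromosome 12, 108000001 to 109000000, where 52 of 56 tested regions were specific to DN3 (adjusted p = 4.84e-44, hypergeometric test). On the same chromosome, 44 consecutive tested regions between 107712842 and 108600841 were specific to DN3, with a summed level of 347.7 ± 26.6 CPM in DN3 and 11.5 ± 2.59 CPM in NMP, the highest of the other 4. The next windows were chromosome 14, 53000001 to 54000000, with 65 of 153 regions, and 54000001 to 55000000, with 52 of 144.

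**Figure D2:**
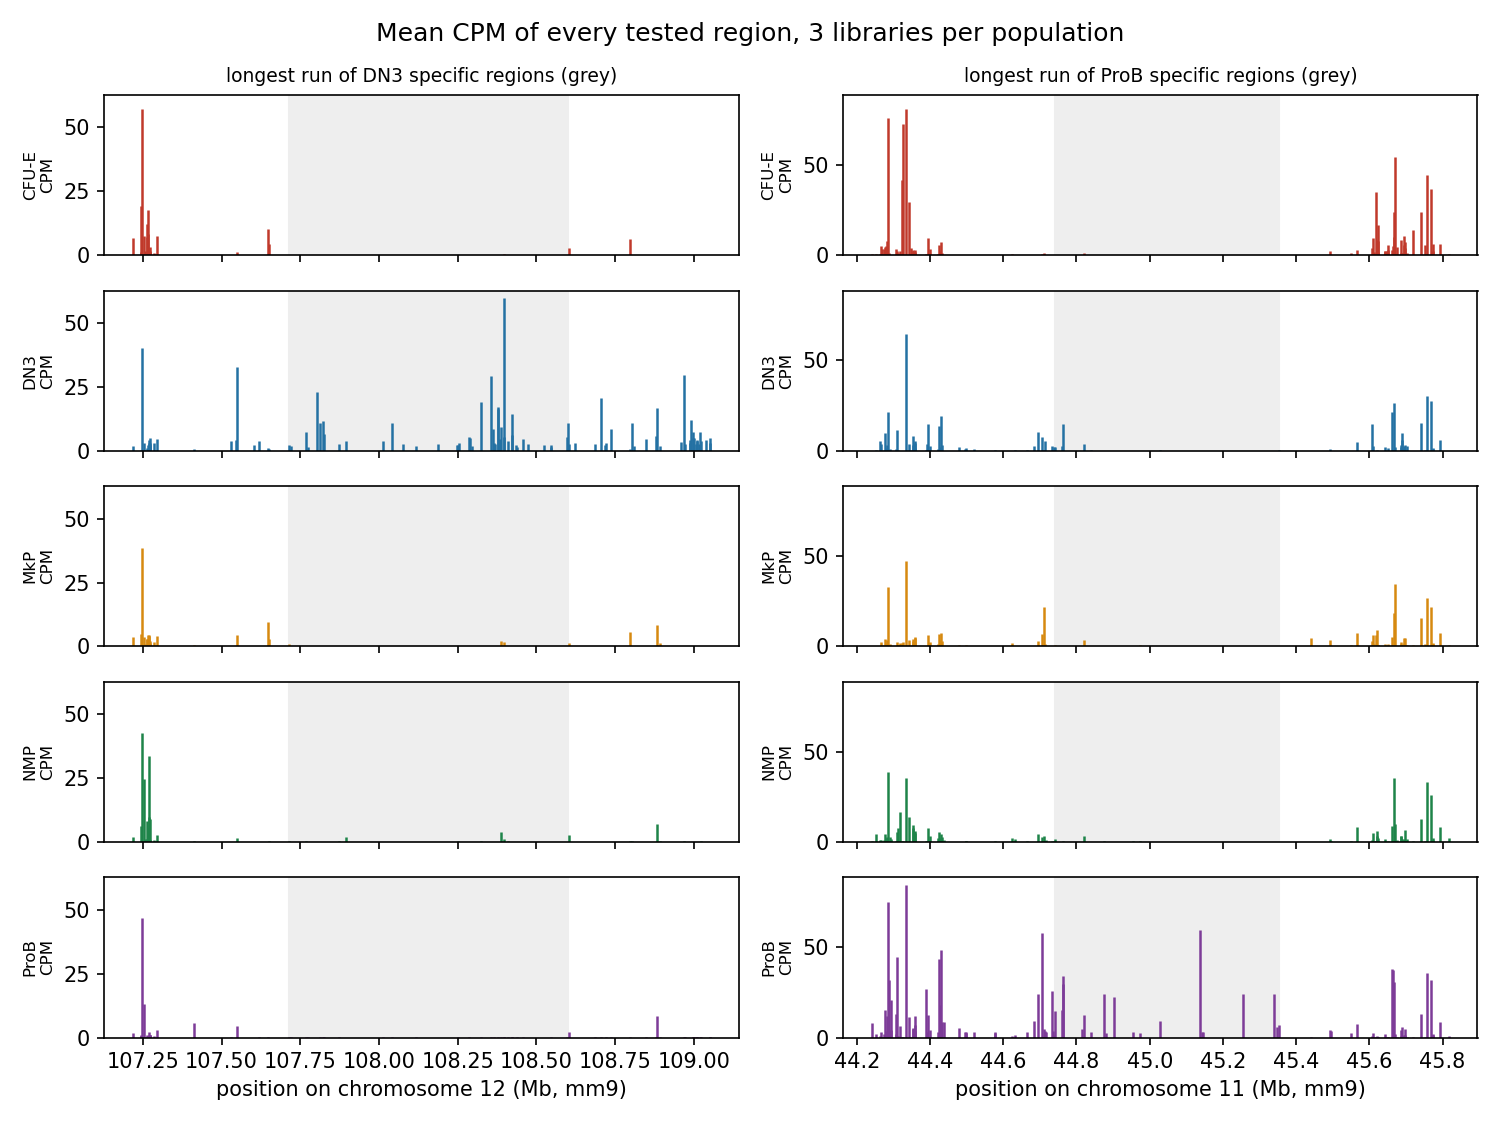
Mean CPM of each tested region (vertical lines at region centres, n = 3 libraries per population) along the longest run of DN3 specific regions on chromosome 12 (left) and the longer by span of 2 runs of 20 ProB specific regions on chromosome 11 (right), with 0.5 Mb on each side and the run shaded grey; positions are in Mb of mm9. The 44 regions of the first run sum to 347.7 CPM in DN3, and the 20 of the second to 304.9 CPM in ProB.

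NMP had 27124 specific regions (15.7%), more than CFU-E. The order turned after quantile normalization (23726 in NMP, 24522 in CFU-E) and with no minimum fold change (33855 in NMP, 35725 in CFU-E). Such ranks hold for the deposited regions, and whether depth shaped which regions were called as peaks is not known. The NMP specific regions held 19.4% ± 0.459 of the NMP counts. Their mean level was 7.26 ± 0.270 CPM in NMP and 1.48 ± 0.167 CPM in MkP, which ranked next at 61.2% of them. MkP replicate 1 had 1.63 CPM at these regions, MkP replicate 2 had 1.51 CPM and MkP replicate 3 had 1.30 CPM. Chromosome 6, 6446329 to 6447291, had 15.9 ± 1.64 CPM in NMP and 0.292 ± 0.232 CPM in MkP, a log2 fold change of 5.74 ± 0.30 (adjusted p = 8.22e-49, edgeR's quasi-likelihood test). The region at chromosome 5, 54643257 to 54643725, had 5.27 ± 0.577 CPM, 76.0-fold the MkP level (20.7 to 633). Chromosome 1 held 2 of the named regions, at 127239705 to 127240176 with 4.49 ± 0.455 CPM and at 173753407 to 173753621 with 2.87 ± 0.721 CPM. The last, chromosome 5, 106638617 to 106639109, had 3.00 ± 1.32 CPM. Windows with an excess numbered 157, led by chromosome 3, 131000001 to 132000000, with 29 of 47 regions (adjusted p = 1.01e-09, hypergeometric test). On chromosome 6, 24 consecutive tested regions between 122871086 and 123210657 were specific to NMP.

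ProB had 14146 specific regions (8.20%), which held 19.4% ± 0.473 of the ProB counts. Their mean level of 15.2 ± 0.330 CPM in ProB was the highest of the 5 sets, against 2.28 ± 0.0773 CPM in DN3 and 2.10 ± 0.0304 CPM in NMP. NMP ranked next at 30.3% of these regions, DN3 at 28.1%, CFU-E at 23.6% and MkP at 18.1%. At chromosome 16, 22938527 to 22940035, ProB had 108.8 ± 4.49 CPM and NMP 0.402 ± 0.288 CPM, a log2 fold change of 8.13 ± 0.18 (adjusted p = 2.39e-283, edgeR's quasi-likelihood test). Chromosome 8, 123963953 to 123965138, had 70.1 ± 1.07 CPM and a log2 fold change over NMP of 8.11 ± 0.22. On chromosome 12, 115420652 to 115421494, the level was 57.1 ± 2.81 CPM, with a log2 fold change over MkP of 8.22 ± 0.24. Chromosome 6, 50956088 to 50956697, had 19.7 ± 1.80 CPM, 563-fold the MkP level (101 to 22308, from 1 count in MkP). Chromosome 7, 128601624 to 128601940, had 6.93 ± 0.886 CPM in ProB and 0 counts elsewhere, at least 49.2-fold higher than in CFU-E. Against DN3 the bound is lower, since 3 counts correspond to 0.252 CPM there and to 0.141 CPM in CFU-E. Of 122 windows with an excess, the first was chromosome 11, 44000001 to 45000000, with 42 of 94 regions (adjusted p = 1.15e-17, hypergeometric test). Chromosome 6, 68000001 to 69000000, had 19 of 26 and chromosome 12, 115000001 to 116000000, had 29 of 73. Runs of 20 consecutive specific regions lay on chromosome 11 at 82172834 to 82390588 and at 44741810 to 45353320, the longer of them by span, with 304.9 ± 5.46 CPM in ProB and 24.96 ± 4.49 CPM in DN3.

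MkP had 7276 specific regions (4.22%), the smallest number. They held 5.43% ± 0.143 of the MkP counts, with a mean level of 6.36 ± 0.270 CPM in MkP, 1.24 ± 0.0147 CPM in NMP and 1.14 ± 0.0116 CPM in CFU-E. NMP ranked next at 38.8% of them and CFU-E at 36.1%. Chromosome 1, 51356941 to 51357715, had 37.1 ± 3.73 CPM in MkP and 0.217 ± 0.242 CPM in NMP, a log2 fold change of 7.64 ± 0.26 (adjusted p = 7.66e-108, edgeR's quasi-likelihood test). Chromosome 1, 128982471 to 128983114, had 11.9 ± 0.734 CPM and a log2 fold change over NMP of 6.00 ± 0.35. The region at chromosome 1, 79843434 to 79843954, had 11.5 ± 0.0711 CPM, 68.4-fold the DN3 level (18.8 to 567). Chromosome 15, 69520891 to 69521419, had 9.23 ± 0.187 CPM, 65.5-fold that in CFU-E (22.2 to 320). Chromosome 13, 85917495 to 85918003, had 6.58 ± 1.26 CPM, 67.3-fold that in ProB (18.4 to 560). MkP specific regions were in excess in 81 windows, led by chromosome 7, 141000001 to 142000000, with 18 of 46 regions (adjusted p = 1.74e-10, hypergeometric test).

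Neighbouring regions are not independent, and with 1 region per 5 kb the windows in excess fell to 53 for CFU-E, 47 for DN3, 30 for MkP, 57 for NMP and 33 for ProB. Without the count filter, 185 windows were in excess for ProB.

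**Figure D3:**
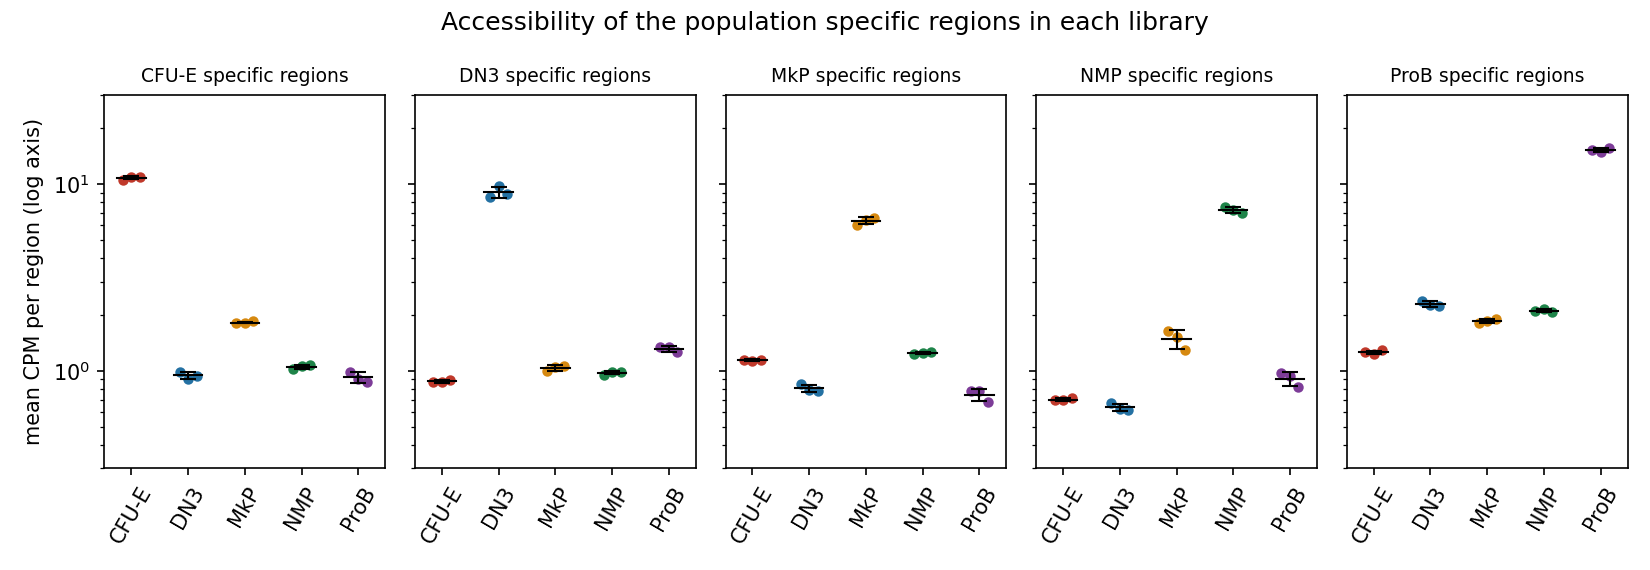
Mean CPM per region (log axis) of each library at the 5 sets of population specific regions, with points for libraries and black bars for the mean ± SD of 3 libraries. Each set is highest in its own population by construction, and the NMP specific set is next highest in MkP, at 1.30 to 1.63 CPM.

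Each pair of populations was compared to find the regions that set them apart. Scaling moved the median log2 fold change over all tested regions, which for MkP against ProB was 0.29 with TMM, 0.67 with total counts alone and 0.08 after quantile normalization, so counts per direction are relative to the scaling. Within the LK gate, CFU-E and MkP differed at 89929 regions, 40433 higher in CFU-E and 49496 higher in MkP. The CFU-E side was led by chromosome 2, 148508594 to 148508889, with 8.07 ± 0.620 CPM in CFU-E, at least 76.3-fold higher than in MkP. Chromosome 6, 71559853 to 71560255, was at least 53.5-fold higher. In the other direction, chromosome 1, 51356941 to 51357715, was at least 264.8-fold higher in MkP, and chromosome 4, 119542902 to 119543524, with 15.03 ± 0.450 CPM, at least 106.6-fold. CFU-E took 44.96% of the calls, against 34.0% with scaling by total counts alone and 50.1% with no minimum fold change, where the larger side turned.

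CFU-E and NMP were the pair with the most calls, 108186, with 46752 higher in CFU-E and 61434 higher in NMP. CFU-E took 43.2% of the calls, and 40.8% to 48.8% under the alternatives. Chromosome 3, 14808208 to 14808969, had 28.3 ± 4.98 CPM in CFU-E, at least 274.7-fold higher than in NMP, and chromosome 11, 53360907 to 53361546, was at least 222.6-fold higher. NMP had 26.3 ± 4.32 CPM at chromosome 9, 89562099 to 89563056, at least 182.3-fold more than CFU-E. Chromosome 2, 68633902 to 68634870, was at least 174.8-fold higher in NMP.

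MkP and NMP differed at 74363 regions, 31714 higher in MkP and 42649 higher in NMP. The larger side changed with the scaling, since MkP took 42.6% of the calls with TMM and 52.0% with total counts alone. Chromosome 15, 69520891 to 69521419, was at least 90.6-fold higher in MkP, and chromosome 11, 62040431 to 62040858, with 7.62 ± 0.509 CPM, at least 75.4-fold. Chromosome 3, 75081331 to 75081768, had 2.99 ± 1.10 CPM in NMP and was at least 26.5-fold higher there. For chromosome 16, 52371990 to 52372468, the bound was 25.8-fold.

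The lymphoid pair, DN3 and ProB, had the fewest calls, 67730, split into 32899 higher in DN3 and 34831 higher in ProB. This rank depends on the threshold, since at 8-fold or more MkP and NMP had the fewest, 17159, against 29541 for DN3 and ProB. DN3 was also the shallowest population, which limits the calls in its pairs. DN3 took 48.6% of them, and 45.9% to 55.9% under the alternatives, of which 6 put DN3 on the larger side, the fit without DN3 replicate 3 (50.1%) among them. Chromosome 15, 63086755 to 63087741, was at least 402.8-fold higher in DN3, and chromosome 10, 26078396 to 26079199, with 31.7 ± 3.65 CPM, at least 219.4-fold. ProB had 153.1 ± 5.28 CPM at chromosome 4, 139299244 to 139300596, at least 608.2-fold more than DN3. ProB also had 99.3 ± 3.12 CPM at chromosome 5, 35656570 to 35658164, at least 394.3-fold more.

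CFU-E and DN3 differed at 97883 regions, 53449 higher in CFU-E and 44434 higher in DN3. CFU-E took 54.6% of the calls, against 49.3% with total counts alone, 49.2% after quantile normalization and 49.8% with libraries thinned to equal totals. CFU-E had 72.4 ± 3.20 CPM at chromosome 14, 75071880 to 75072971, at least 287.6-fold more than DN3, and 63.7 ± 7.01 CPM at chromosome 9, 123864835 to 123865767, at least 251.9-fold more. DN3 had 29.6 ± 2.08 CPM at chromosome 12, 108967102 to 108968045, at least 209.6-fold more than CFU-E. Chromosome 2, 117243975 to 117244781, was at least 189.3-fold higher in DN3.

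CFU-E and ProB differed at 98916 regions, 52299 higher in CFU-E and 46617 higher in ProB. CFU-E took 52.9% of the calls, against 48.0% after quantile normalization. Chromosome 1, 195490683 to 195491532, had 47.6 ± 1.63 CPM in CFU-E and was at least 328.8-fold higher than in ProB, and chromosome 18, 36599515 to 36600266, was at least 307.2-fold higher. ProB had 71.3 ± 0.756 CPM at chromosome 13, 41497764 to 41498593, at least 507.05-fold more than CFU-E. A bound of 439.3-fold held at chromosome 1, 33338301 to 33339381.

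DN3 and MkP differed at 85780 regions, 32443 higher in DN3 and 53337 higher in MkP. DN3 took 37.8% of the calls, and 34.2% to 46.8% under the alternatives. DN3 was at least 293.3-fold higher at chromosome 5, 93292810 to 93293509, and at least 231.0-fold higher at chromosome 19, 11622132 to 11622771, where it had 24.7 ± 7.12 CPM. MkP had 39.1 ± 2.16 CPM at chromosome 1, 190211290 to 190212625, at least 155.8-fold more than DN3. Its level at chromosome 3, 122406918 to 122407831, was 32.1 ± 3.63 CPM, at least 125.95-fold more.

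DN3 and NMP differed at 93397 regions, 35500 higher in DN3 and 57897 higher in NMP. DN3 had 41.1 ± 4.82 CPM at chromosome 10, 42418711 to 42419341, at least 400.5-fold more than NMP, and 21.4 ± 3.60 CPM at chromosome 6, 71291054 to 71291632, at least 208.1-fold more. NMP had 51.3 ± 1.64 CPM at chromosome 17, 26634134 to 26635008, at least 202.9-fold more than DN3. Chromosome 11, 87603261 to 87604173, was at least 174.6-fold higher in NMP. DN3 took 38.0% of the calls, and 49.7% after quantile normalization.

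MkP and ProB differed at 82995 regions, 51268 higher in MkP and 31727 higher in ProB. MkP took 61.8% of the calls, against 71.5% with total counts alone and 52.5% after quantile normalization. MkP had 21.8 ± 1.49 CPM at chromosome 4, 5652074 to 5653171, at least 150.6-fold more than ProB, and was at least 129.1-fold higher at chromosome 6, 5106397 to 5107396. ProB had 34.3 ± 2.61 CPM at chromosome 11, 44763787 to 44764264, within its run of 20 specific regions with the longer span and at least 325.0-fold more than in MkP. Chromosome 3, 67300234 to 67300911, was at least 276.2-fold higher in ProB.

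NMP and ProB differed at 85286 regions, 54371 higher in NMP and 30915 higher in ProB. NMP had 40.3 ± 3.06 CPM at chromosome 1, 180975942 to 180976999, at least 278.2-fold more than ProB, and was at least 190.4-fold higher at chromosome 16, 44988728 to 44989542. ProB had 72.2 ± 3.91 CPM at chromosome 3, 53781256 to 53781823, 2125-fold the NMP level (381 to 83976, from 1 count in NMP). Chromosome 4, 151004447 to 151005224, was at least 162.2-fold higher in ProB. NMP took 63.8% of the calls, and 50.9% after quantile normalization.

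All 40 region calls named for the pairs had an adjusted p of at most 3.63e-19 (edgeR's quasi-likelihood test, Benjamini-Hochberg adjustment within the pair, n = 3 per population). The bounds depend on depth, and against DN3 they are lower for the same level than against the other populations.

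**Figure D4:**
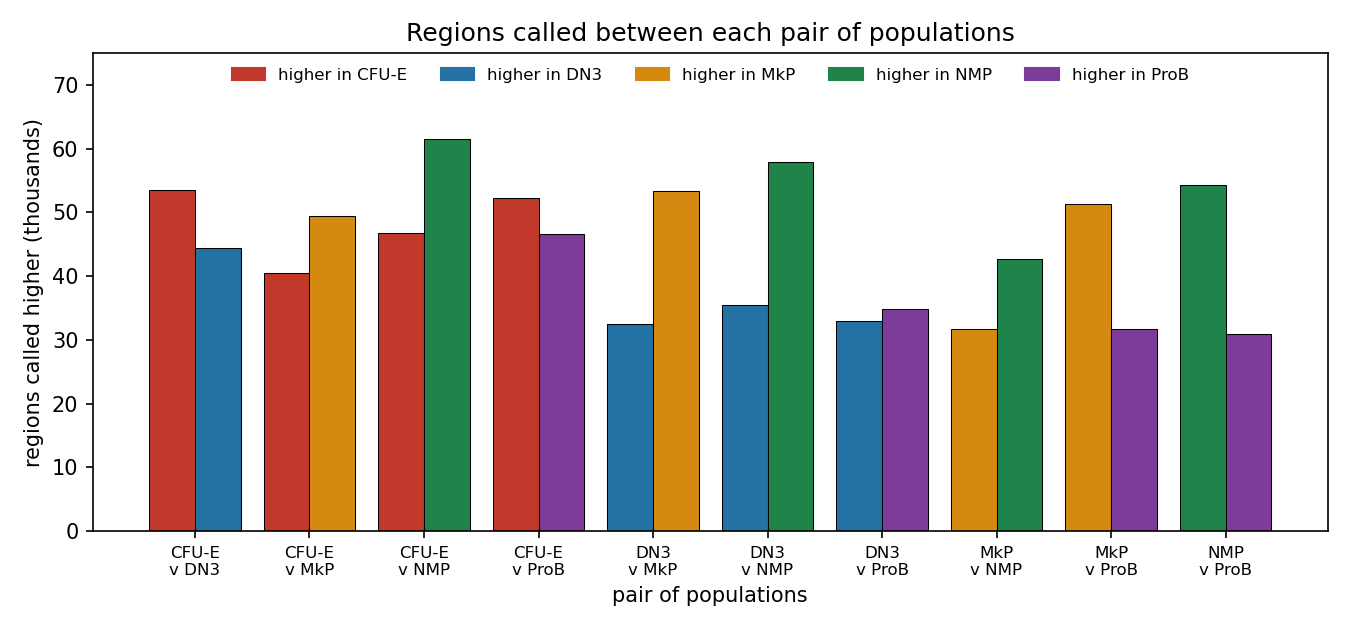
Number of regions, in units of 1000, called between each pair of populations, with 1 bar per direction coloured by the population in which the regions were higher (edgeR, adjusted p under 0.05 and at least 2-fold). At this threshold, CFU-E and NMP have the most calls, 108186, and DN3 and ProB the fewest, 67730.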

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

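Thinning to equal totals, 1 region per 5 kb and windows moved by 0.5 Mb were chosen after the data were seen, and the other alternatives before the data were examined. Of the values that these alternatives gave for the 21 counts of regions and windows, 518 stayed within 1.5 times the reported count and 6 did not. With 1 region per 5 kb, the windows with an excess of specific regions fell to 53 for CFU-E (from 154), 47 for DN3 (from 109), 30 for MkP (from 81), 57 for NMP (from 157) and 33 for ProB (from 122), where fewer regions were tested by construction. Without the count filter, ProB had 185 windows in excess, and the cause was not tested.

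Of the values for the named regions, 1599 kept their direction and their side of the threshold. The exception was the DN3 specific region on chromosome 1, 128081735 to 128082078, which DESeq2 did not call, with an adjusted p of 0.192, against 1.37e-22 to 5.43e-12 under the other 23 alternatives. Its log2 fold change stayed large, at 7.57 in DESeq2 and 8.17 in the main fit. The cause was not tested. No named region reversed its direction under the alternatives run. For the 65 named calls, the values with no minimum fold change repeat the main fit and pass by construction. For the pairs, some fits leave out a library of a population outside the comparison, which tests them little.

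The number of regions differing among the populations was 153005 with libraries thinned to equal totals and 211747 without the count filter, which tested more regions. When each library was left out in turn, this number ran from 157794 to 158274, and that of MkP specific regions from 7031 (without MkP replicate 3) to 7464 (without MkP replicate 1). Total counts alone gave 9588 MkP specific regions, quantile normalization 8514 and DESeq2 6879, against 7276 reported. Each of these settings kept MkP lowest of the 5 populations. CFU-E, not NMP, had the most specific regions after quantile normalization, 24522 against 23726, and with no minimum fold change, 35725 against 33855.

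Replicate numbers were not treated as pairs. Deviations from the population mean correlated between libraries with the same number at a median r of 0.0057 across regions, which are not independent replicates, with 0 of 30 pairs above 0.1, against a median of -0.0028 between libraries with other numbers. Small as these values were, 12 of the 15 libraries were closest to those with their own number. Counting error lowers such correlations, so an effect shared by libraries with the same number is not excluded. With the replicate number as a block, 158124 regions differed among the populations. Depth limits the folds that can be bounded, since 3 counts over a population correspond to 0.252 CPM in DN3 and to 0.102 CPM in NMP. Gene list tests and motif tests, with their alternatives, were not run, as no annotation or genome sequence on mm9 was used here.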

Other observations

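Regions higher in 2 populations than in each of the other 3 joined some pairs more than others. If the regions above the other 3 had been drawn independently for each population, 2977 would have been higher in both CFU-E and MkP, and 9286 were, of which 3610 were not also specific to 1 of them. For MkP and NMP, 3376 would have been and 9511 were, with 4368 not specific to 1 population. For DN3 and ProB these values were 2599, 6250 and 3374. CFU-E and NMP had 1864, fewer than the 4745 of independent draws. Both counts of a pair use the same comparison libraries, and the effect of that sharing was not separated. Regions lower in a single population than in each of the others numbered 13627 for CFU-E, 6041 for DN3, 4245 for ProB, 1960 for NMP and 575 for MkP. Of these, 9022, 3147, 2422, 1134 and 334 were not also specific to another population.

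The test of background in MkP replicate 1, the comparison with carry-over in a fixed share and the 3 tests of the low number of MkP specific regions were chosen after the result was seen. NMP specific regions were more open in MkP replicate 1 than in MkP replicate 3, by 25.3% ± 0.453 (SE over regions). Each side is 1 library, and SEs over regions, which are not independent, do not cover the spread between libraries. A higher background would raise the other sets too. However, the CFU-E specific set changed by -2.36% ± 0.260, the DN3 set by -6.70% ± 0.369 and the ProB set by -5.02% ± 0.306. The MkP specific set changed by -8.10% ± 0.243, and a difference in scaling between the libraries would move all these values. A rise in proportion to the MkP level would give a larger excess where MkP replicate 2 was more open, yet the ratio of excesses was 0.596 ± 0.0213. NMP cells carried into the MkP sort would give the same excess relative to NMP at every NMP level, and the ratio of the highest to the lowest tertile was 1.02 ± 0.0341. Carry-over in a fixed share would also give 0.758 in place of 0.596, a difference of -0.162 ± 0.0204 (SE over regions), so the values do not all go with it. Carry-over stays open because a difference in scaling between the libraries would move this ratio too, by an amount that was not tested. The gate, CD150+ and CD41+, is set to leave out NMP, which lack both, but no purity of the sort was given. Cells within the gate with NMP-like open regions remain an untested biological alternative.

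MkP had the fewest specific regions. Depth of the counts alone would not account for this, because after thinning to equal totals the next lowest count was 1.92 times that of MkP. Thinning kept the same regions, so an effect of depth on peak calling was not tested. The smallest such ratio over 3 other scalings was 1.33, with total counts alone. Carry-over of CFU-E and NMP cells cannot be told apart from a property of MkP, since leaving out MkP replicate 1 gave 1.03 times as many regions and carry-over common to the 3 libraries would not show. The MkP gate requires CD150 and CD41, which CFU-E and NMP both lack. No purity of the sort was given, so the gate does not decide whether such cells were carried over. Chromatin that MkP share with CFU-E and NMP may also lower the count. Of the regions higher in 2 populations and specific to neither, CFU-E and MkP shared 3610 and MkP and NMP 4368. DN3 and MkP shared 1072, and MkP and ProB 582. Such regions cannot count as specific to MkP, but whether sharing explains the low number was not tested.

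Chromosome X took 1.54% to 1.55% of the counts in ProB and 1.72% to 1.80% in the other libraries. A different number of X chromosomes that lowered this share would lower accessible X regions with it. Regions over 1000 bp on X differed from autosomal ones by -0.0126 ± 0.0279 (median log2 difference, ProB against the other 4, SE), above the bound of -0.1 set beforehand by more than 2 SE, which argues against it. The 3144 narrower X regions, tested after the result was seen, differed by -0.0574 ± 0.0178, lower than autosomal ones but also above that bound by more than 2 SE. ProB specific regions, which held 19.4% of the ProB counts, made up 5.34% of the tested X regions and 8.20% of all tested regions. Whether this accounts for the lower share was not tested, nor was any other explanation.

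Other groupings of the libraries were compared with the real one. Among 40 groupings of the 15 libraries into 5 groups of 3, the real one included, 1 had as many regions differing among groups, the real one with 158347, and the highest other had 45245. The specific regions of CFU-E (25544), DN3 (16686) and NMP (27124) were each reached by 1 of the 40, with 15324 as the highest other. A share of 1 of 40 lies under the bound of 0.05 set beforehand, but it is the smallest possible here and does not exclude chance. Groupings that mix populations put the differences between them inside groups, which lowers their calls, so the contrast in size is no further support. For MkP (7276) and ProB (14146), 2 of the 40 reached the count, a share of 0.05, which by itself does not exclude chance. The other grouping that reached them, with 15324, kept the 3 CFU-E libraries together, so it holds the signal of that population. The groupings that kept no population whole called 0 regions in edgeR's test, against up to 47237 at an unadjusted p under 0.05 with the same range.

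For each pair of populations, 1 of the 10 splits of the 6 libraries, the real one, gave the most regions. A share under 0.1 is not possible with 10 splits. The real splits gave 96253 regions for CFU-E and DN3, 88901 for CFU-E and MkP, 107763 for CFU-E and NMP, 97123 for CFU-E and ProB, and 83732 for DN3 and MkP. They gave 92316 for DN3 and NMP, 66457 for DN3 and ProB, 74166 for MkP and NMP, 81518 for MkP and ProB, and 84143 for NMP and ProB. The highest other split gave 0 regions in edgeR's test for every pair, and 889 to 1763 at an unadjusted p under 0.05. Each other split mixes both populations in its groups, so the difference between them counts as spread and lowers the calls. The contrast in size with the real splits therefore does not measure chance.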
